A study of Homo sapiens with 2 samples.

How the data were processed

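RNA of the uveal melanoma lines Mel285 and MP46 was extracted with an RNeasy Mini kit and made into Illumina stranded mRNA libraries, per the labels' protocols, with 1 sample per line. The deposited table gives TPM values (transcript abundance corrected for length and scaled to a fixed total), 1 value per gene symbol and line, and the submitters' processing notes name kallisto 0.48.0 and GRCh38. The transcript annotation, the way transcripts were summed to symbols and any filter are not given in the sources used here. These choices decide how reads shared by paralogs, pseudogenes and alternate sequences were divided, so values of such genes are uncertain. TPM sets each library to a fixed total, so a higher share of a few genes lowers the values of all others. The listed values summed to 98.13% of the full TPM total in Mel285 and 97.48% in MP46, and the 100 most abundant genes took 35.4% and 31.0% of the sum. TPM keeps no read depth, so no counting error could be given for any value. A value of 0 is reported as listed at 0, with no fold.

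The groups are the cell lines named by the sample titles. Of 35587 symbols, 426 were left out (Y-linked genes, XIST and TSIX), and 35060 of the 35161 others were matched by symbol or synonym to the RefSeq gene table of GRCh38.p14 or to GENCODE 29, which gave positions and gene types. Of them, 19760 were protein-coding. The difference of a gene was log2 of (MP46 TPM + 1) over (Mel285 TPM + 1). A gene was called higher or lower where this was at least 1 in size and its TPM was at least 1 in at least 1 line. With 1 library per line there is no p-value. Each of 34 gene lists was described by the counts of genes higher, lower and within 2-fold and by the percentile of its median among 10000 random lists of the same size, drawn with seed 1 from genes passing the same filter and matched on mean log2(TPM + 1) in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5, and lists with fewer than 3 such genes got no percentile. The same was done for the genes of each of the 22 autosomes with at least 1 TPM in both lines. Percentiles describe these libraries and are not tests across replicates.

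The lists, the rules and 10 of the alternatives for lists were fixed before the data were examined. Genes named in the results are BAP1 and PLIN2, the members with the largest differences in each list (up to 4, or up to 8 for lipid droplet, fatty acid and melanocyte lists, and all for lists of 9 or fewer genes), the 10 protein-coding genes with the largest differences in each direction among those with at least 10 TPM in a line, and the 5 most abundant genes of each line. Mitochondrially encoded and ribosomal protein genes were left out of the last groups. Some genes that this rule names are not reported here. Alternatives were a pseudocount of 0.1 or 5 TPM, a median log ratio of 0 between the lines over 9160 genes with at least 5 TPM in both, removal of mitochondrially encoded and ribosomal protein genes or of the 100 most abundant genes with rescaling, no filter or a filter of 5 TPM, random lists without matching, protein-coding genes alone, the mean of list members, and a 4-fold threshold for counts. Leaving out the MHC (GABBR1 to KIFC1, chromosome 6, 29602238 to 33409896) was added after the data were seen.

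The percentile was tested on simulated data for the comparison of MP46 with Mel285, with differences of 14858 genes shuffled within expression bins. Shuffling removes any shared variation of genes, so the simulation does not cover lists whose genes vary together. Of 100 random lists of 5, 10 or 30 genes, 8, 4 and 5 lay outside the central 95%. With every member raised by 1 on the log2 scale, 39, 69 and 97 of 100 lists of these sizes lay above percentile 97.5, so short lists can miss such a shift. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.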

Results

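RNA was measured by stranded, poly(A)-selected RNA-seq in 2 established human uveal melanoma cell lines, with 1 library each. Uveal melanoma is a cancer of the pigment cells of the eye. The labels give Mel285 a wild-type genotype and call MP46 BAP1 negative. BAP1 encodes a nuclear deubiquitinase that acts on histone H2A and is a tumour suppressor in this cancer. The series title is about adipophilin, the lipid droplet coat protein encoded by PLIN2, so the comparison asked how MP46 differed from Mel285, first in PLIN2 and then in genes of lipid and energy metabolism and of cell identity. Each value below is a TPM from 1 library, so no difference has a replicate check, and BAP1 status cannot be separated from any other difference between the lines. TPM keeps no read depth, so the depth of both libraries is unknown. Genes are called higher or lower where the lines differed by at least 2-fold on the log2(TPM + 1) scale and at least 1 line reached 1 TPM. The log2 difference is given as MP46 minus Mel285, and on this scale it understates the difference of genes with low values.

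The table held 35587 gene symbols. Of the genes analysed, 13197 reached 1 TPM in Mel285 and 13424 did so in MP46, and 8651 and 8941 reached 10 TPM. Mitochondrially encoded genes took 14.8% of the summed TPM in Mel285 and 10.4% in MP46, and ribosomal protein genes took 12.2% and 12.4%. FTH1, the ferritin heavy chain, led the remaining genes in both lines, with 16997 TPM in Mel285 and 18411 TPM in MP46. The next most abundant genes of Mel285 were TMSB10 (5922 TPM), which encodes an actin-binding thymosin, EEF1A1 (5407 TPM), ACTG1 (4665 TPM) and GAPDH (3978 TPM). In MP46 they were EEF1A1 (8511 TPM), the melanosome matrix gene PMEL (6357 TPM), MTRNR2L12 (4241 TPM), a nuclear copy of mitochondrial sequence whose reads are uncertain, and the melanin synthesis gene TYRP1 (4019 TPM).

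BAP1 (chromosome 3, 52401008 to 52410008, GRCh38) had 29.3 TPM in Mel285 and 0.134 TPM in MP46, a log2 difference of -4.74. Its lower value in MP46 goes the same way as the labels. PLIN2 (chromosome 9, 19108388 to 19127492, GRCh38) had 202.0 TPM in Mel285 and 0.280 TPM in MP46, a log2 difference of -7.31. Among lipid droplet proteins it had the largest difference of the 31 members that reached 1 TPM.

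Of those 31 lipid droplet genes, 11 were lower in MP46, 7 were higher and 13 lay within 2-fold. PLIN3, which encodes another perilipin coat protein, had 131.4 TPM in Mel285 and 20.6 TPM in MP46. The triglyceride synthesis gene DGAT2 (24.1 and 4.80 TPM), the monoglyceride lipase gene MGLL (15.3 and 2.47 TPM) and the lysophosphatidylcholine acyltransferase gene LPCAT2 (16.0 and 2.06 TPM) were also lower, while METTL7B had 5.48 TPM in Mel285 and was listed at 0 in MP46. In the opposite direction, HSD17B11, a droplet-associated dehydrogenase, had 13.3 TPM in Mel285 and 101.4 TPM in MP46, and the lipid droplet hydrolase gene PNPLA3 had 5.41 and 35.1 TPM. The median log2 difference of the list was -0.39, at percentile 1.07 among 10000 random lists matched on expression. The percentile passed 2.5 when mitochondrially encoded and ribosomal protein genes were removed (2.98) and when the 100 most abundant genes were removed (3.01).

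**Figure D1:**
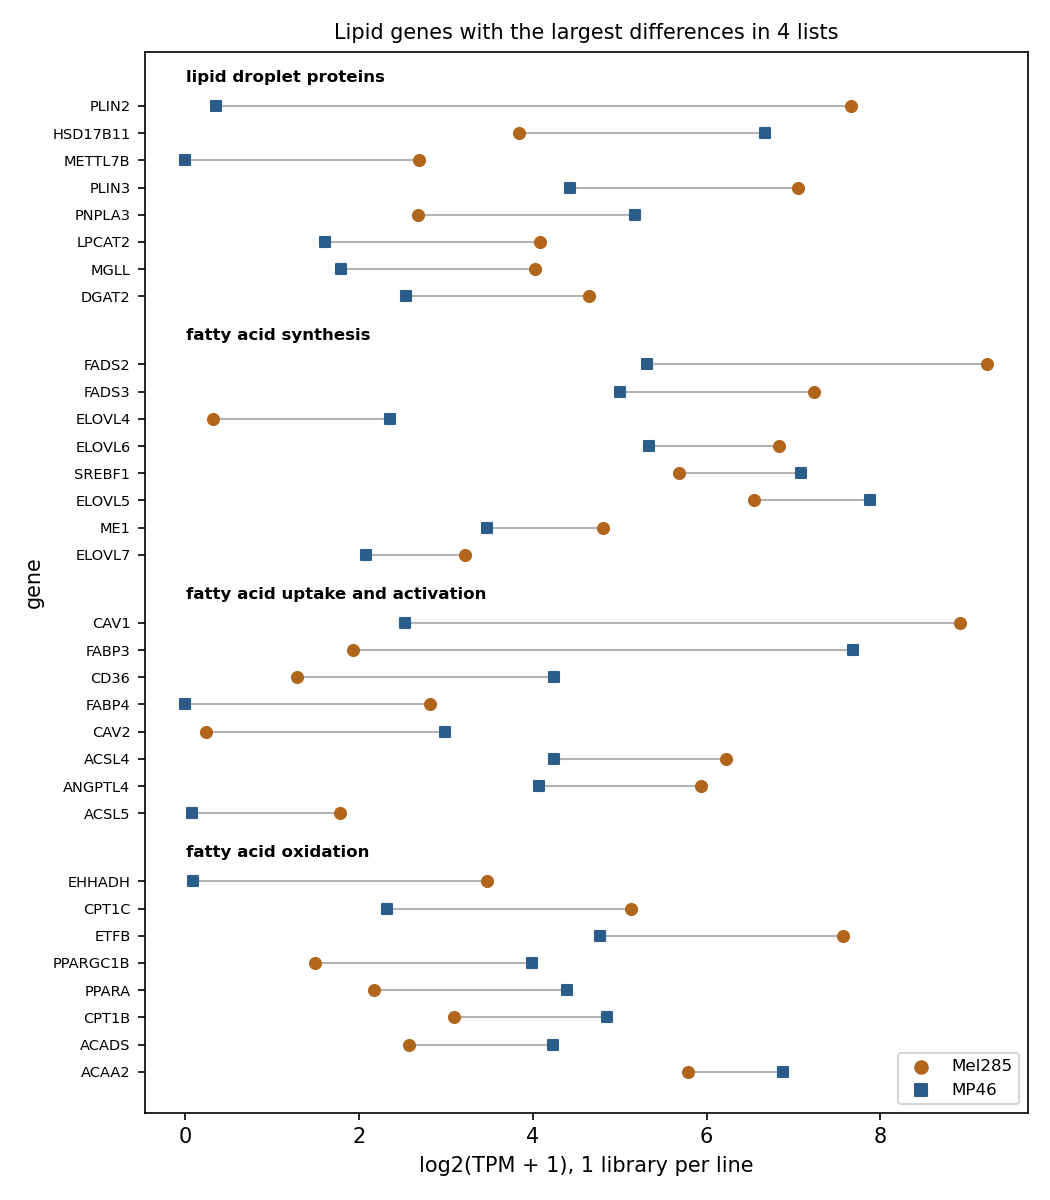
Level of each lipid gene named in the 4 lists as log2(TPM + 1) on the horizontal axis, with a circle for Mel285 and a square for MP46, 1 library per line and no error. PLIN2 lies at 202.0 TPM in Mel285 and 0.280 TPM in MP46, while HSD17B11 and FABP3 lie higher in MP46.

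Genes that bring fatty acids into cells and activate them differed in both directions: of 20, 8 were lower in MP46 and 6 were higher. CAV1, which encodes the main coat protein of caveolae, had 483.0 TPM in Mel285 and 4.77 TPM in MP46, and the acyl-CoA ligase gene ACSL4 had 73.9 and 17.9 TPM. The fatty acid binding protein genes went apart, since FABP3 had 2.82 TPM in Mel285 and 204.6 TPM in MP46 while FABP4 had 6.07 TPM in Mel285 and was listed at 0 in MP46. The fatty acid transporter gene CD36 was higher in MP46 (1.45 and 18.0 TPM), as was CAV2 (0.178 and 6.94 TPM). ANGPTL4, which encodes an inhibitor of lipoprotein lipase, was lower (60.1 and 15.8 TPM), as was ACSL5 (2.43 and 0.0576 TPM), though not with a pseudocount of 5 TPM (log2 difference -0.56). The list median was -0.45, at percentile 1.77. This call ended under 6 of the alternatives, with percentiles up to 18.28 with no filter on low values and 14.15 for the mean of the members.

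Of 24 fatty acid synthesis genes, 16 lay within 2-fold, 5 were lower in MP46 and 3 were higher, with a median of -0.01 at percentile 27.43. The desaturase gene FADS2 had 600.4 TPM in Mel285 and 38.7 TPM in MP46, and its relative FADS3 had 149.4 and 31.1 TPM. The elongase genes ELOVL6 (112.9 and 39.4 TPM) and ELOVL7 (8.30 and 3.22 TPM) and the malic enzyme gene ME1 (27.1 and 10.1 TPM) were lower. ELOVL5 (92.2 and 234.4 TPM), ELOVL4 (0.2503 and 4.13 TPM) and SREBF1, which encodes the sterol-regulated transcription factor SREBP-1 (50.3 and 135.4 TPM), were higher. With a pseudocount of 5 TPM, ELOVL7 (-0.70) and ELOVL4 (0.80) lay within 2-fold. Of 31 genes of cholesterol synthesis and uptake, 6 were lower in MP46 and 3 were higher, with a median of -0.32 at percentile 0.87. The cholesterol efflux transporter gene ABCA1 had 13.1 TPM in Mel285 and 0.190 TPM in MP46, and the synthesis genes MSMO1 (219.7 and 59.9 TPM) and MVD (101.5 and 31.4 TPM) were lower. MYLIP, which encodes the ligase that degrades the LDL receptor, was higher (1.24 and 9.12 TPM). The cholesterol percentile was 3.06 against random lists not matched on expression and 2.77 for the mean of the members.

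Among 30 fatty acid oxidation genes, 21 lay within 2-fold, 6 were higher in MP46 and 3 were lower. The median was 0.01 at percentile 20.24. EHHADH, a peroxisomal oxidation enzyme gene, had 10.1 TPM in Mel285 and 0.0682 TPM in MP46. CPT1C (33.9 and 4 TPM) and the electron transfer flavoprotein gene ETFB (189.2 and 26.4 TPM) were also lower. PPARA, a fatty acid-activated receptor gene (3.53 and 19.97 TPM), its coactivator relative PPARGC1B (1.82 and 15.0 TPM), CPT1B (7.53 and 28.03 TPM), ACADS (4.96 and 17.8 TPM) and ACAA2 (54.3 and 116.8 TPM) were higher, ACAA2 by less than 2-fold with the median log ratio set to 0 (0.88).

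Of 56 nuclear-encoded oxidative phosphorylation genes, 48 lay within 2-fold (median 0.09, percentile 59.55), as did 21 of 27 genes of the tricarboxylic acid cycle and glutamine use (median 0.20, percentile 58.47). COX7A2 (123.0 and 548.2 TPM) and NDUFV2 (100.2 and 291.1 TPM) were higher in MP46, while NDUFA8 (175.5 and 47.0 TPM) and ATP5F1D (180.7 and 58.4 TPM) were lower. The mitochondrial enzyme genes IDH2 (98.2 and 30.7 TPM) and GOT2 (128.7 and 43.5 TPM) were lower and DLD (71.0 and 175.1 TPM) was higher. Of 13 mitochondrially encoded genes, 10 lay within 2-fold (median -0.50, percentile 3.56). MT-ND2 had 11656 TPM in Mel285 and 4299 TPM in MP46, and MT-ND6 (1740 and 4931 TPM) and MT-ND5 (1665 and 3644 TPM) were higher in MP46, while MT-ATP8, whose gene overlaps MT-ATP6, had 24661 and 12826 TPM, within 2-fold. With the median log ratio set to 0, MT-ND5 lay within 2-fold (0.91) and MT-ATP8 did not (-1.16).

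Of 23 glycolysis genes, 7 were lower in MP46 and 5 were higher (median -0.10, percentile 17.64). The lactate transporter gene SLC16A3 had 615.5 TPM in Mel285 and 47.7 TPM in MP46, and the glucose transporter gene SLC2A1 had 130.5 and 15.7 TPM. ENO2 was lower (65.1 and 8.54 TPM) and ALDOC was higher (7.99 and 66.6 TPM). Hypoxia response genes were lower more often, 9 of 24 against 3 higher, with a median of -0.59 at percentile 0.10. LOX, a collagen cross-linking enzyme gene (1532 and 1.52 TPM), and STC2 (946.2 and 2.24 TPM) were lower, while the HIF prolyl hydroxylase gene EGLN3 was higher in MP46 (0.579 and 17.0 TPM). Among 22 genes of lipid peroxidation and ferroptosis, 5 were higher and 4 were lower (median 0.05, percentile 36.80). POR, the cytochrome P450 reductase gene, had 46.6 TPM in Mel285 and 477.6 TPM in MP46. GCLC (18.3 and 102.5 TPM) and the cystine transporter subunit gene SLC3A2 (151.5 and 700.9 TPM) were higher, and the metalloreductase gene STEAP3 (57.4 and 5.79 TPM) was lower.

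Pigment cell genes had the largest median difference of the lists. Of 28 melanocyte lineage and pigment genes, 26 were higher in MP46, none was lower and 2 lay within 2-fold, with a median log2 difference of 6.90 at percentile 100. PMEL had 0.771 TPM in Mel285 and 6357 TPM in MP46, and TYRP1 had 0.497 and 4019 TPM. The lineage transcription factor genes SOX10 (582.4 TPM in MP46) and PAX3 (0.0171 and 257.7 TPM) followed, with SOX10 listed at 0 in Mel285. It was 1 of 3 list members at 0 there, whose call as higher was fixed by the 1 TPM filter. EDNRB, the endothelin receptor gene of melanoblasts (0.350 and 691.7 TPM), CAPN3 (0.413 and 370.7 TPM) and ABCB5 (0.00797 and 255.1 TPM) were also higher. Neural crest and glial markers were higher in 6 of 12 and lower in 3, with a median of 1.51 at percentile 99.66. NES (0.478 and 174.6 TPM), the neuregulin receptor gene ERBB3 (0.555 and 140.4 TPM), SOX8 (0.198 and 38.1 TPM) and MBP (10.3 and 201.9 TPM) showed the largest differences. The percentile of this list was 96.10 with mitochondrially encoded and ribosomal protein genes removed and 93.52 with no filter on low values.

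**Figure D2:**
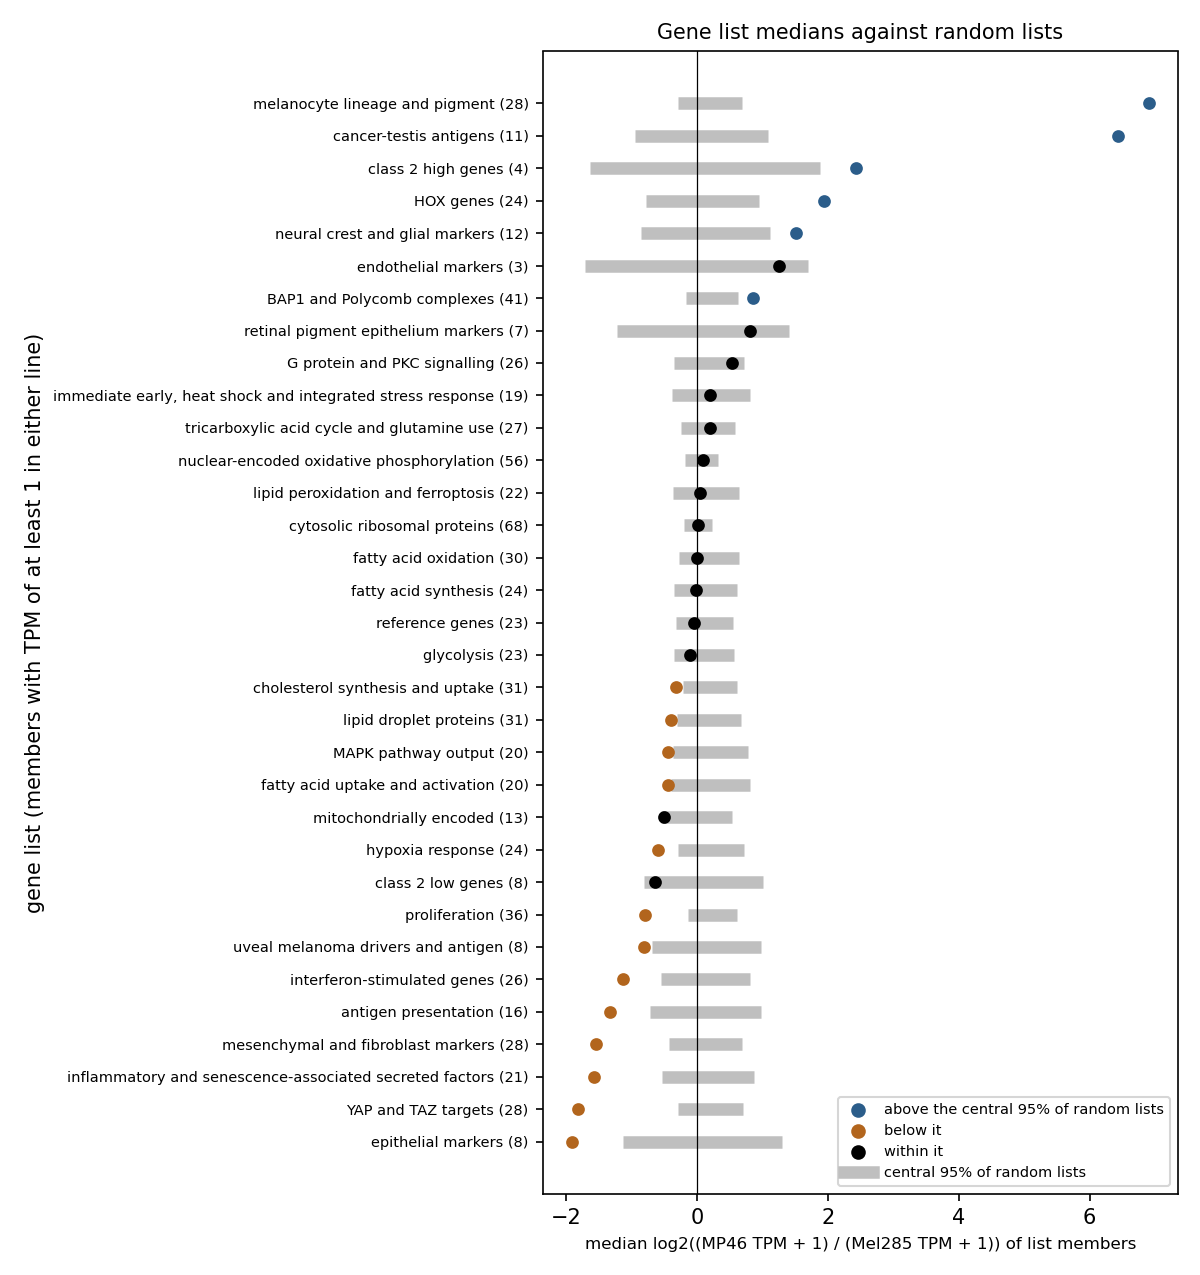
Median log2 difference of the members of each gene list on the horizontal axis, MP46 minus Mel285, with the number of members in brackets and a grey bar for the central 95% of 10000 random lists of the same size matched on expression. Melanocyte genes (median 6.90) and cancer-testis antigens (6.43) lie farthest to the right, and epithelial markers (-1.91) and YAP and TAZ targets (-1.82) farthest to the left.

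Mesenchymal and fibroblast markers went the other way, with 17 of 28 lower in MP46 and 5 higher (median -1.53, percentile 0.00). The surface glycoprotein gene THY1 had 585.1 TPM in Mel285 and 0.0119 TPM in MP46. TGFBI (270.7 and 0.195 TPM), the receptor tyrosine kinase gene AXL (248.2 and 0.139 TPM) and the homeobox gene PRRX1 (80.2 and 0.0967 TPM) were lower. Targets of the YAP and TAZ coactivators were lower in 17 of 28 and higher in 2 (median -1.82, percentile 0.00). Besides AXL, they were led by IGFBP3 (751.7 and 2.43 TPM), the tissue factor gene F3 (206.4 and 0.135 TPM) and MYOF (152.6 and 1.01 TPM). Of 8 epithelial markers, 5 were lower, among them the simple-epithelium keratin genes KRT18 (287.9 and 0.0767 TPM) and KRT8 (421.8 and 1.07 TPM) and KRT7, which had 22.4 TPM in Mel285 and was listed at 0 in MP46. Another 2 were higher. The splicing regulator gene ESRP1 was higher (0.182 and 32.7 TPM), as was CDH1 (0.159 and 21.6 TPM), so these markers did not go 1 way. The list median was -1.91 at percentile 0.25. The epithelial percentile was 30.73 with no filter on low values.

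Markers of the retinal pigment epithelium went both ways, while no endothelial or immune cell marker that reached 1 TPM was lower in MP46. Of 7 retinal pigment epithelium markers, 3 were higher in MP46 and 3 were lower (median 0.82, percentile 84.96), with SERPINF1 (1.93 and 183.5 TPM), BEST1 (4.19 and 168.9 TPM) and MERTK (2.21 and 61.5 TPM) higher and the eye-field factor gene PAX6 (20.1 and 0.757 TPM) lower. Among 3 endothelial markers, EMCN (0.877 and 34.7 TPM) and ERG (0.0818 and 1.59 TPM) were higher and KDR had 1.27 and 1.74 TPM (median 1.26, percentile 89.15). ERG lay within 2-fold with a pseudocount of 5 TPM (0.38). Of the immune cell markers, CD68 alone reached 1 TPM (169.7 and 397.8 TPM), so no percentile was computed for that list.

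Among 8 genes, made up of drivers of uveal melanoma and its antigen PRAME, 1 was higher in MP46, 2 were lower and 5 lay within 2-fold (median -0.81, percentile 1.47). The 2 lower genes were PLCB4 and BAP1, and the labels already call MP46 BAP1 negative. PRAME had 240.6 TPM in MP46 and was listed at 0 in Mel285. PLCB4, which encodes a phospholipase C downstream of Gq proteins, had 151.3 TPM in Mel285 and 3.75 TPM in MP46. The Gq family genes GNAQ (47.4 and 23.6 TPM) and GNA11 (57.1 and 35.2 TPM), the initiation factor gene EIF1AX (169.5 and 88.3 TPM) and the splicing factor genes SF3B1 (197.2 and 300.3 TPM) and SRSF2 (197.0 and 238.9 TPM) lay within 2-fold. GNAQ (-1.19) and EIF1AX (-1.15) passed 2-fold with the median log ratio set to 0. Both also passed it with mitochondrially encoded and ribosomal protein genes removed (-1.05 and -1.01) and with the 100 most abundant genes removed (-1.07 and -1.02). GNAQ passed it with a pseudocount of 0.1 TPM too (-1.001), so its call within 2-fold is borderline. The percentile of this list was 13.00 for the mean of its members. Class 2 is the expression class of uveal melanoma with the higher risk of metastasis. Of the class 2 high genes, HTR2B (0.0294 and 31.7 TPM) and CDH1 (0.159 and 21.6 TPM) were higher in MP46, and ECM1 (26.7 and 39.9 TPM) and RAB31 (41.9 and 48.8 TPM) lay within 2-fold, with a median of 2.42 at percentile 99.20. Of 8 class 2 low genes, ROBO1 was lower (10.6 and 1.97 TPM), MTUS1 (0.287 and 2.47 TPM) and EIF1B (26.4 and 71.2 TPM) were higher and 5 lay within 2-fold (median -0.64, percentile 5.27). Those 5 were LMCD1 (21.9 and 10.9 TPM), SATB1 (9.38 and 4.71 TPM), LTA4H (60.0 and 38.0 TPM), FXR1 (227.5 and 146.1 TPM) and ID2 (149.2 and 192.1 TPM). LMCD1 (-1.14) and SATB1 (-1.05) passed 2-fold with the median log ratio set to 0, and MTUS1 lay within 2-fold with a pseudocount of 5 TPM (0.498). LMCD1 also passed 2-fold with mitochondrially encoded and ribosomal protein genes removed (-1.02) and with the 100 most abundant genes removed (-1.04).

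Genes of BAP1 partners and Polycomb repressive complexes were higher in MP46 in 17 of 41 cases and lower in 4, BAP1 among them (median 0.86, percentile 99.87). The Polycomb recruitment gene JARID2 had 5.14 TPM in Mel285 and 53.95 TPM in MP46. RING1 had 102.5 TPM in MP46 and was listed at 0 in Mel285, but it lies in the major histocompatibility complex (MHC), where values of many genes stood apart, and without it 16 of 40 genes were higher and 4 were lower (median 0.86). HOX genes, classical Polycomb targets, were higher in 18 of 24 and lower in 1, with a median of 1.95 at percentile 100, and 10 of the 24 were listed at 0 in Mel285. HOXC4 (0.116 and 26.2 TPM), HOXB4 (0.219 and 22.0 TPM), HOXD4 (0.0462 and 16.5 TPM) and HOXC6 (0.596 and 23.5 TPM) had the largest differences. The spans of HOXC4 and HOXC6 overlap, so their values need not be separate measurements. Of 20 cancer-testis antigens measured, 11 reached 1 TPM, all 11 were higher in MP46, and 10 of them were listed at 0 in Mel285 (median 6.43, percentile 100). A gene listed at 0 in 1 line, here, among the HOX genes or in any other list, passed the 1 TPM filter through the other line alone. Its call as higher or lower was therefore fixed by the filter. XAGE1B had 308.1 TPM, CTAG2 205.7 TPM and CTAG1B 98.8 TPM in MP46, and near-identical copies of these genes share reads, so the split between copies is uncertain.

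Immune and secretory genes were mostly lower in MP46. Of 26 interferon-stimulated genes, 14 were lower and 4 were higher (median -1.13, percentile 0.02), with IFITM3 (712.3 and 33.4 TPM) and IFI44L (15.7 and 0.0243 TPM) lower, IFITM1 at 10.4 TPM in Mel285 and listed at 0 in MP46, and USP18 higher (0.295 and 12.8 TPM). Of 21 inflammatory and senescence-associated secreted factors, 11 were lower and 3 were higher (median -1.58, percentile 0.00). Besides IGFBP3, the collagenase gene MMP1 was lower (74.4 and 0.112 TPM), whereas GDF15, a stress-induced cytokine gene, had 2.71 TPM in Mel285 and 1140 TPM in MP46. Of 16 antigen presentation genes, 9 were lower and 3 were higher (median -1.33, percentile 0.05), but 9 of the 16 lie in the MHC. Those include HLA-E (34.2 TPM in MP46, listed at 0 in Mel285), TAPBP (20.9 and 1.503 TPM) and the immunoproteasome gene PSMB8 (9.48 and 0.173 TPM), while of the 7 genes elsewhere 4 were lower and 0 were higher (median -1.53). The antigen presentation percentile was 4.52 with no filter on low values and 2.57 for the mean of the members.

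Proliferation genes were lower in 11 of 36 and higher in 2 (median -0.80, percentile 0.00), with GINS2 (30.2 and 4.13 TPM), MKI67 (53.0 and 17.5 TPM), RRM2 (167.9 and 57.9 TPM) and CCNB1 (234.8 and 82.2 TPM) lower in MP46. Of 20 genes of MAPK pathway output, 7 were higher and 5 were lower (median -0.44, percentile 1.57). FOSL1, an AP-1 transcription factor gene, had 300.4 TPM in Mel285 and 2.21 TPM in MP46, and EPHA4 had 19.7 and 2.34 TPM, while the feedback inhibitor gene SPRY4 was higher (4.18 and 35.6 TPM) and IER3, in the MHC, had 12.3 TPM in MP46 and was listed at 0 in Mel285. The MAPK percentile was 23.78 for the mean of the members. G protein and PKC signalling genes were higher in 10 of 26 and lower in 4 (median 0.53, percentile 89.35). RASGRP3, a Ras activator gene downstream of Gq signalling, had 2.36 TPM in Mel285 and 398.4 TPM in MP46, and ADCY1 had 0.225 and 28.2 TPM, while RGS4, a G protein inhibitor gene, had 426.0 and 0.109 TPM.

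Most ribosomal protein and reference genes lay within 2-fold. Of 68 cytosolic ribosomal protein genes, this held for 58, 6 were higher and 4 were lower (median 0.01, percentile 56.12). RPS12 was higher (1089 and 4268 TPM) and RPL35 (2401 and 748.5 TPM), RPL13 (3246 and 1038 TPM) and RPL7A (1371 and 611.5 TPM) were lower, and all such genes share reads with pseudogenes. Of 23 reference genes, 17 lay within 2-fold, with a median of -0.05 at percentile 24.55 and a mean of the opposite sign, 0.06. HPRT1 (100.4 and 38.8 TPM) and ACTB (3711 and 1552 TPM) were lower, and YWHAZ (765.3 and 1798 TPM) and RAB7A (144.4 and 320.3 TPM) were higher, RAB7A by less than 2-fold with the median log ratio set to 0 (0.93). Of 19 genes in a list of immediate early, heat shock and integrated stress response genes, 6 were higher and 3 were lower (median 0.20, percentile 48.77). The immediate early genes NR4A1 (9.57 and 133.7 TPM) and FOS (4.29 and 35.5 TPM) were higher in MP46, as were CHAC1 (6.35 and 115.5 TPM) and ASNS (31.0 and 142.0 TPM), targets of ATF4 in the integrated stress response.

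Among protein-coding genes with at least 10 TPM in a line, leaving out mitochondrially encoded and ribosomal protein genes, the gene with the largest difference toward Mel285 was TMSB4X, an actin-binding thymosin gene, with 2616 TPM in Mel285 and 0.0938 TPM in MP46, which has processed pseudogenes that can share its reads. The matrix and growth factor genes EFEMP1 (1643 and 0.0159 TPM), CCDC80 (1148 and 0.454 TPM), CHRDL1 (350.2 and 0.0558 TPM) and FGF2 (431.4 and 0.347 TPM) followed with LOX, THY1 and RGS4, together with the retinaldehyde dehydrogenase gene ALDH1A3 (386.1 and 0.0967 TPM) and BEX1 (423.7 and 0.258 TPM). Toward MP46, besides PMEL, TYRP1, SOX10, EDNRB and XAGE1B, the named genes were the transcriptional coregulator gene CITED1 (0.234 and 902.2 TPM), the apoptosis inhibitor gene BIRC7 (0.236 and 755.9 TPM), the apolipoprotein gene APOE (1.64 and 1272 TPM) and the actin-severing protein gene SCIN (0.370 and 561.6 TPM). In all, 14858 genes reached 1 TPM in at least 1 line. Of these, 3722 (25.1%) were higher in MP46, 2788 (18.8%) were lower and 8348 lay within 2-fold. Across these genes, which are not independent replicates, log2(TPM + 1) of the lines had a Pearson r of 0.72 and a Spearman rho of 0.72. The median log2 difference of all of them was 0.21, and with the median log ratio set to 0 the counts were 3048 higher and 3279 lower, a share higher of 48.2% against 57.2%.

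Of the 34 lists, 6 lay above and 13 below the central 95% of random lists, 14 lay within it and 1 was too small. By chance 1.65 would lie outside if lists, and the genes within each, were independent. Genes of a list can vary together, so these counts do not measure an excess over chance. The calls of 9 lists changed under at least 1 alternative.

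Medians differed between chromosomes. Over 11763 genes with at least 1 TPM in both lines, the median log2 difference was 0.19, and the medians of 16 of the 22 autosomes lay outside the central 95% of random gene sets, 9 above and 7 below. With no filter on low values 1 autosome, chromosome 22, lay outside, since genes listed at 0 in both lines then bring the other medians to 0. Genes of chromosomes 22 (289 genes, median 1.09), 18 (167 genes, 1.08), 6 (535 genes, 0.95) and 14 (388 genes, 0.92) were highest in MP46 relative to Mel285. Those of chromosomes 9 (498 genes, -0.65), 11 (652 genes, -0.46) and 16 (579 genes, -0.34) were lowest. Chromosome 3, which carries BAP1 and whose loss is frequent in this cancer, had a median of 0.15 over 636 genes, at percentile 18.38. PLIN2 lies on chromosome 9.

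**Figure D3:**
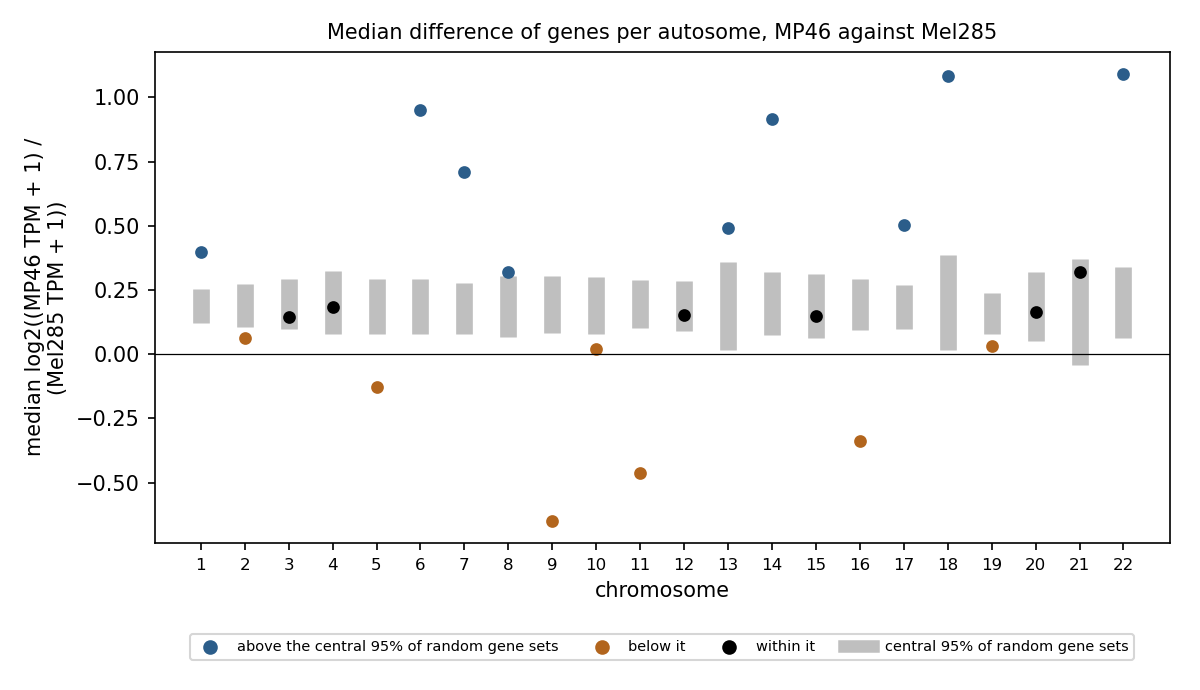
Median log2 difference of the genes of each autosome on the vertical axis, MP46 minus Mel285, with a grey bar for the central 95% of 10000 random gene sets of the same size matched on expression. Chromosomes 22 (1.09) and 18 (1.08) lie highest and chromosome 9 (-0.65) lowest, while chromosome 3 (0.15) lies within its bar; with no filter on low values, chromosome 22 alone lay outside.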

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

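The setting without the MHC was chosen after the data were seen and the others before. Settings that need several columns per line (limma over columns, leaving out a column) were not run, since each line has 1 column. No called direction reversed. BAP1 stayed lower in MP46 under its 5 alternatives, from -2.74 (pseudocount of 5 TPM) to -6.97 (pseudocount of 0.1 TPM), and PLIN2 from -5.29 to -9.05. Over the 171 named genes, 809 alternative values kept the call, 8 lost it (ACAA2, MT-ND5 and RAB7A with the median log ratio set to 0, and ACSL5, ELOVL4, ELOVL7, ERG and MTUS1 with a pseudocount of 5 TPM) and 12, at GNAQ, EIF1AX, LMCD1, SATB1 and MT-ATP8, gained it. Of the 33 lists with a percentile, 24 kept their call under every alternative run and 9 changed under at least 1.

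Counts of genes fell to 2329 higher and 1717 lower with a pseudocount of 5 TPM and to 1268 and 1155 at 4-fold, by construction. Without the MHC they were 3666 and 2779. With a pseudocount of 5 TPM, the percentile was 2.99 for fatty acid uptake and 97.46 for neural crest markers. With mitochondrially encoded and ribosomal protein genes removed, it was 2.98 for lipid droplet proteins, 2.84 for epithelial markers and 96.10 for neural crest markers. With the 100 most abundant genes removed, it was 3.01 for lipid droplet proteins and 97.25 for neural crest markers. With no filter on low values, it was 18.28 for fatty acid uptake, 30.73 for epithelial markers, 93.52 for neural crest markers, 4.52 for antigen presentation and 2.48, now below 2.5, for mitochondrially encoded genes. With a filter of 5 TPM fatty acid uptake was at 10.62, and with protein-coding genes alone at 2.58. Against random lists not matched on expression, fatty acid uptake was at 3.15, cholesterol synthesis at 3.06, uveal melanoma drivers at 3.63 and MAPK output at 3.34. For the mean of members they were at 14.15, 2.77, 13.00 and 23.78, and antigen presentation at 2.57. The cause of these changes in percentile was not tested. With no filter on low values, 1 autosome lay outside the central 95% in place of 16, since genes listed at 0 in both lines bring medians to 0. Read depth is not known from TPM, so its limit on low genes could not be set.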

Other observations

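All tests below, and the choice of the genes and families described, were made after the results were seen. Gene families differed in both directions. Of 449 groups of coding genes with a shared symbol stem and at least 5 members at 1 TPM, 18 lay above and 33 below the central 95% of random lists. By chance 22.5 would lie outside if groups, and the genes within each, were independent. Some stems, such as C (211 genes), FAM (154 genes) and AC (142 genes), join genes that need not be related, so these counts do not describe families alone. The largest medians toward MP46 were those of the MAGEA (7 of 7 higher, median 5.79), PNMA (4 of 5 higher, 3.92) and HOXD genes (6 of 6 higher, 3.55), and MAGEA and HOXD genes are also in the lists of cancer-testis antigens and HOX genes. Family members listed at 0 in Mel285, such as MAGEA1 (54.4 TPM in MP46) and PNMA3 (66.0 TPM), passed the filter through MP46 alone. Their call as higher was fixed by it. Of 10 integrin alpha genes, 8 were lower in MP46 and 1 was higher (median -3.29, percentile 0.00), with the laminin receptor genes ITGA3 at 489.2 TPM in Mel285 and 45.1 TPM in MP46, ITGA6 at 135.7 and 11.0 TPM and ITGA7 at 147.0 and 3.26 TPM, and ITGA9 the exception at 0.0173 and 10.2 TPM. Their partners, 7 integrin beta genes, lay within the random range (2 higher, 1 lower, percentile 25.91). All 11 protocadherin beta genes were lower (median -2.97). Of 11 protocadherin gamma A genes 4 were higher and 2 were lower (percentile 88.94), and of 6 gamma B genes 0 were higher and 4 were lower (median -1.40, percentile 2.60). Also lower were all 9 pregnancy-specific glycoprotein genes (median -2.37), among them PSG4 at 232.2 TPM in Mel285 and listed at 0 in MP46, so its call was fixed by the filter. Near-identical copies in these families and in MAGEA share reads. Of 5 metallothionein genes, which encode metal-binding proteins, MT2A (3513 and 12.5 TPM), MT1X (289.3 and 8.74 TPM) and MT1E (51.2 TPM, listed at 0 in MP46) were lower, MT1F had 7.07 and 3.64 TPM, and MT1A had 2.62 TPM in MP46 and was listed at 0 in Mel285.

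Some imprinted genes also had different values, a group for which no list was tested. The paternally expressed genes SNRPN, SNURF and NDN on chromosome 15 had 238.4, 26.03 and 4.597 TPM in MP46, and all 3 were listed at 0 in Mel285. SNRPN and SNURF overlap and share reads. PEG3, a paternally expressed gene of chromosome 19, went the other way with 3.73 TPM in Mel285 and 0.117 TPM in MP46, and PEG10 had 51.2 and 25.3 TPM, within 2-fold.

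PLIN2 and BAP1 were near 0 in MP46. Loss of a segment of 1 Mb on each side is argued against by the neighbours that were counted, which need not be all coding genes there. The coding genes counted within 1 Mb had a median log2 difference of -0.71 for PLIN2 (5 genes, all at 1 TPM or more in MP46) and 0.38 for BAP1 (38 genes, 35 at 1 TPM or more). PLIN2 reads given to other perilipin genes are argued against too, because PLIN1, PLIN3, PLIN4 and PLIN5 summed to 21.9 TPM in MP46 and 132.2 TPM in Mel285. A smaller deletion remains open, and the gene next to BAP1, PHF7, had the lowest difference of the 38 neighbours counted (3.31 and 0.153 TPM). Whether low PLIN2 goes with BAP1 loss, with low levels of mesenchymal genes or with another property of the line is not tested by 1 library per line.

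Melanocyte genes were near 0 in Mel285, a line labelled as uveal melanoma. Fibroblasts that make collagens I and III are argued against, since the highest of COL1A1, COL1A2, COL3A1, DCN and LUM was COL1A1 at 8.30 TPM, but other mesenchymal cells stay open, with THY1 at 585.1 TPM, FN1 at 2630 TPM, LOX at 1532 TPM and 17 of 28 markers of that list higher in Mel285. Keratin-rich epithelial cells cannot be told apart from a melanoma line with keratins, because KRT8 (421.8 TPM), KRT18 (287.9 TPM), KRT80 (29.5 TPM) and KRT7 (22.4 TPM) go with them while the highest of EPCAM, CDH1, KRT19, KRT5 and KRT14 was KRT19 at 0.730 TPM. Some genes of the melanocyte list were present in Mel285, with MITF at 21.6 TPM, GPNMB at 244.4 TPM and RAB27A at 53.0 TPM, against 282.2, 1113 and 45.6 TPM in MP46. A share of pigmented cells with levels like those of MP46 is argued against as their source, since PMEL, TYRP1 and SOX10 allow at most 0.01235% of such cells while MITF would need 7.653%, GPNMB 21.97% and RAB27A 116.3%. RAB27A was higher in Mel285 than in MP46, so no share of such cells could reach its value and its outcome was fixed. A melanoma state with low pigment genes may account for these values, and so may a line of another origin, a mixture of cells without pigment genes or a wrong label, and 1 library could not decide between them.

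Genes of the MHC differed more often than others, and many of them serve basic cell functions. Of 62 coding genes with at least 5 TPM in a line, 20 (32.3%) were at least 8-fold apart, against 8.9% of 10882 genes elsewhere with no transcripts on alternate sequences of the assembly, and 21 were under 1 TPM in Mel285, among them the lipid synthesis gene AGPAT1 (0.0256 and 152.0 TPM), the ubiquitin ligase gene RNF5 (0.102 and 100.4 TPM) and the trafficking gene VPS52 (0.183 and 45.7 TPM). Loss of the whole region is argued against by 20 genes with at least 10 TPM in Mel285, such as TUBB (404.1 TPM), and alternate copies anywhere in the genome by the 8.9% (32 of 360) of genes elsewhere that have them. Reads divided among alternate copies of the MHC in the transcript index, with some copies left out of the table, remain an open candidate explanation. In GENCODE 29, 61 of the 62 genes have such copies, but the index is not given in the sources used here. Of the 8 genes elsewhere with at least 3 times as many alternate as primary transcripts, 0 were 8-fold apart. So few genes cannot decide for or against it. A difference between the lines in this region cannot be told apart from such a division of reads. There, 43 of the 57 genes outside the antigen presentation list were higher in MP46 and 2 were lower (median 2.09). Some genes were near 0 in both lines, such as HLA-C (0.0559 and 0.00684 TPM) and HSPA1A (listed at 0 in both). The minimum of 5 TPM leaves them out of these counts, and the cause of their low values was not tested.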
